A study of Mus musculus with 6 samples.

How the data were processed

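RNA of 6 OCCM-30 cultures, 3 control and 3 PTH, was measured on 6 arrays. Per the file headers, the arrays were read in 1 scan and the spots were quantified with Agilent Feature Extraction 11.0.1.1 under a 1-colour protocol. The deposited values used are spot intensities, background-subtracted and detrended within each array, per the file headers, and not normalised between arrays. The array design is annotated on mm9, per the file headers. Groups were taken from the labels, which call the samples biological replicates.

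Each array file held 62939 spots. The 1439 control spots and 300 spots named as negative were left out. Spots marked as non-uniform or as population outliers were left out, and the spots of 1 probe were averaged on the log2 scale. The log2 intensity minus the array's 75th percentile was tested with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend, two-sided, Benjamini-Hochberg adjustment). A probe was tested if it was well above background on all arrays of at least 1 group and had at least 2 usable arrays per group, which left 37011. The minimum of 2 usable arrays was added after the files were seen. A floor on detection or a bound on a fold was not needed for the probes named, which were detected on every array.

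Most probes are not paired with a gene, so genes could not be counted and only probes are given. The 15 accessions were matched to symbols without versions through a RefSeq table (assembly GRCm38.p6), and no coordinates are printed because the array uses another build. The rule for named genes, fixed before the data were examined, takes up to 10 genes in each direction among those past the threshold, up to 5 noncoding transcripts in each direction, up to 4 members of each gene list, and 19 genes always. If under 5 pass in a direction it takes the 5 with the smallest unadjusted p. It assumed gene names, which ASMM10P probes lack, so at most 2 identifiers are printed in each direction, and of the 19 genes the 2 with a matched probe, Actb and Gapdh, are given. The 21 gene lists fixed beforehand hold 407 genes, of which 0 had a matched probe, so no list was tested and markers of other cell types were not analysed here.

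The fit was tested on simulated data for this comparison with 37011 probes, of which 200 were changed, with independent noise that lacks the shared variation of the measured arrays. It recovered 84% of the changes of 1 and 97% of those of 2 on the log2 scale, with 10 false calls. When changes were added to the measured PTH arrays, 86% and 99% were recovered, with 25 calls among the other probes, which include any real response. Without added changes the fit called 2 probes. The 200 added changes ease the adjusted threshold for every probe, so these shares may not hold with fewer changes.

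The alternatives were quantile normalization, median centring, 3 other filters on dim probes, the replicate number or the slide row as a block, no intensity trend, array weights, a test against a fold of 1.2, an unadjusted threshold, and leaving out each array in turn. Normexp background correction (offset 50) used the median spot signal, since a mean signal was not among the columns. Normexp on this signal, the slide row, the filter that needs 2 arrays of a group, the block on probes with no missing spot and the fit without the most variable probes were chosen after seeing the data. All arrays share 1 scan, so neither slide nor scan could be a block.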

Results

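Cells of OCCM-30, an immortalised mouse line with properties of cementoblasts, the cells that form the mineralised cementum on tooth roots, were given intermittent parathyroid hormone (PTH) or vehicle. PTH, the hormone that raises blood calcium and acts on bone-forming cells through a G protein-coupled receptor, was present at 100 ng/ml for 6 h of each 24 h cycle. Fresh medium followed for 18 h, and the cells went through 2 cycles. Control cells received 0.1% acetic acid, the vehicle. The labels describe 3 biological replicates per group, which gave 3 control and 3 PTH arrays. RNA was measured on a 1-colour Agilent array made for long noncoding RNA, with 60915 probes after control spots were left out.

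Of these probes, 58141 carry a number that starts with ASMM10P and 923 a number that starts with ASMM10UP, and the files do not pair either kind with a gene. A further 1836 probes are named as lincRNA (long intergenic noncoding RNA): 649 under a mouse name, 1104 under a human name and 83 as exons. The remaining 15 carry a RefSeq accession, and all 15 matched a gene symbol. On the control arrays 63.8% ± 2.08 (SD, n = 3) of the probes were well above background, against 59.1% ± 5.92 (SD, n = 3) on the PTH arrays. PTH replicate 2 had the lowest share, 52.5%, and the highest spread of negative control spots, 42.1 intensity units against 16.0 in control replicate 3, the lowest. No probe was saturated, and the number of arrays limits the precision.

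The first comparison asks which transcripts differ in level between cells given PTH and cells given vehicle. Among 37011 tested probes, 2 rose with PTH and 0 fell (limma, Benjamini-Hochberg adjusted p under 0.05). Both that rose exceeded the 2-fold threshold. The probe ASMM10P011129 was 5.33-fold higher (95% confidence interval 4.80 to 5.92), and its intensity went from 435 ± 35.5 in control to 2169 ± 219 in PTH cells (SD, n = 3 each, limma adjusted p = 2.4e-05). The probe ASMM10P011130 was 3.83-fold higher (95% confidence interval 3.43 to 4.27), from 623 ± 13.7 to 2235 ± 198 (SD, n = 3 each, limma adjusted p = 9.1e-05). On both probes all 3 PTH arrays lay above all 3 control arrays. They were named because there were only 2, and were chosen after their values were seen.

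**Figure D1:**
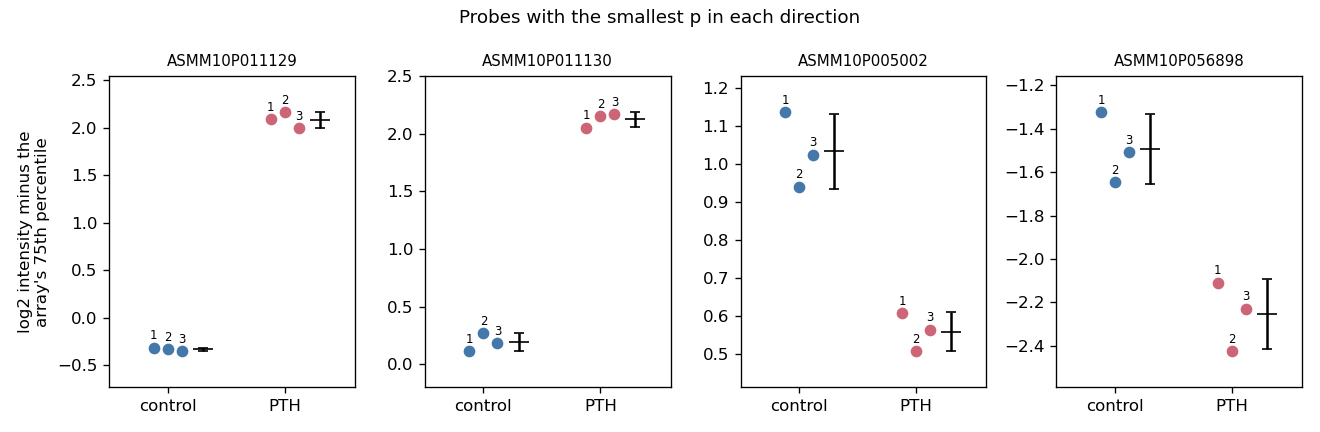
Normalised level (log2 intensity minus the array's 75th percentile) of 4 probes on each control and PTH array, points numbered by replicate, with the mean and SD as a black bar beside them. ASMM10P011129 and ASMM10P011130 were 2.41 and 1.94 higher with PTH on the log2 scale, and the smaller differences of the other two did not pass the adjusted test.

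No probe passed as lower. The 2 probes with the smallest unadjusted p among those lower in PTH did not pass: ASMM10P005002 differed by -0.48 on the log2 scale (95% confidence interval -0.64 to -0.31) and ASMM10P056898 by -0.76 (95% confidence interval -1.03 to -0.49), each with a limma adjusted p of 0.25. At an unadjusted p under 0.05, 5590 probes differed, 3288 higher and 2302 lower in PTH, where chance alone gives 1851. Of these, 185 differed at least 2-fold, 175 higher and 10 lower. Of the 9 other splits of the arrays into 3 and 3, 6 gave 204 to 914 probes, and the 3 that kept control replicates 1 and 3 together gave 2175 to 4923, with up to 158 at least 2-fold. The 3 PTH arrays all lay on one side of the 3 control arrays for 21.2% of the tested probes, against 10% by chance.

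The count depended on 1 control array. Without control replicate 2, 5560 probes passed, 3169 higher and 2391 lower in PTH, and 275 of them at least 2-fold. The unadjusted count was then 12241, 6896 higher and 5345 lower, with 299 at least 2-fold. With the row of the slide as a block, an alternative chosen after seeing the data, 16 passed, 8 in each direction, and within the upper row, which held 3 control arrays and 1 PTH array, 11 passed. Both fits rest on that 1 PTH array, since the lower row held PTH arrays alone, and take it to vary like the others.

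Since the study is about long noncoding RNA, the probes named as lincRNA were counted apart. Of the 1836, 443 were bright enough to test. None of the 443 passed, whether adjusted over all probes or over these probes alone, where the smallest adjusted p in limma was 0.20. At an unadjusted p under 0.05, 39 differed, 25 higher and 14 lower in PTH, against 22.1 by chance, and 5 were at least 2-fold higher. Over all 37011 tested probes 5590 differed, which is a larger share. The middle of their distribution was near 0: the median difference was 0.00 on the log2 scale, with quartiles at -0.10 and 0.13. Without control replicate 2, 36 passed, 30 higher and 6 lower, and 93 had an unadjusted p under 0.05, 64 higher and 29 lower. Over all probes these counts were 5560 and 12241, again larger shares. The shares were not compared at equal signal. Fewer lincRNA-named probes were well above background, 28.2% on control arrays against 63.8% of all probes. The smaller shares therefore do not show a weaker response of lincRNA. The ASMM10P probes were not counted here, since the files do not say which of them are noncoding.

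Detection was counted by kind of probe, and differences between kinds were not tested. Among lincRNA-named probes in control cells, 28.2% ± 2.71 (SD, n = 3) were well above background, and in PTH cells 23.7% ± 5.18 (SD, n = 3). In control cells the share was 65.3% ± 2.06 for ASMM10P and 37.6% ± 1.91 for ASMM10UP probes (SD, n = 3). Within the lincRNA-named probes it was 28.6% ± 2.41 for mouse names, 26.6% ± 2.87 for human names and 47.0% ± 3.61 for exons in control cells (SD, n = 3).

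The genes with a matched symbol are mainly housekeeping genes, and none of the 15 passed. Actb, which encodes cytoplasmic beta-actin, differed by 0.25 on the log2 scale (95% confidence interval -0.11 to 0.61, limma adjusted p = 0.44). Gapdh, a glycolytic enzyme, differed by 0.12 (95% confidence interval -0.04 to 0.29, limma adjusted p = 0.42), and by -0.0048 after quantile normalization, so its direction is not settled. Tbp, the TATA-binding protein of the transcription machinery, had the smallest unadjusted p of the 15, with a difference of -0.21 (95% confidence interval -0.42 to 0.01). Tfrc, the transferrin receptor, differed by 0.12, and Hprt, a purine salvage enzyme, by 0.08. Over the 15 genes the 95% confidence intervals of the PTH to control ratio reached from 0.746 to 1.53. Without control replicate 2, Actb differed by 0.43 and passed, with a limma adjusted p of 0.031. Over its alternatives that adjusted p ran from 0.031 to 0.86.

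**Figure D2:**
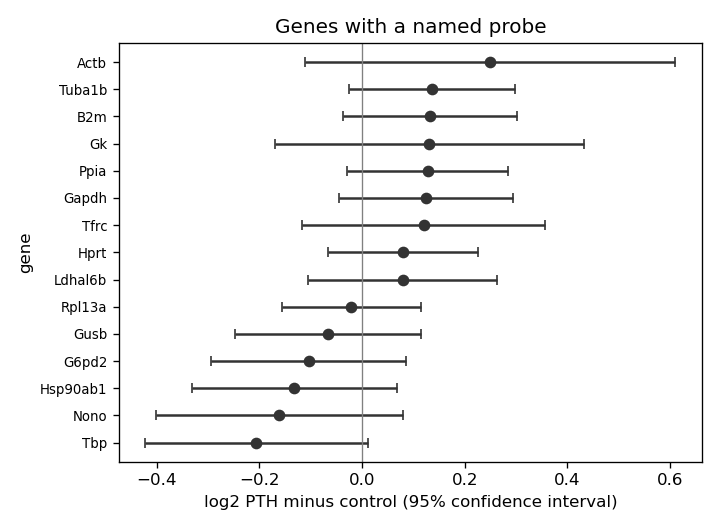
Difference in log2 level between PTH and control cells for the 15 genes with a matched symbol, with 95% confidence intervals as bars and no difference as the vertical line. All 15 intervals include 0, and the largest difference is 0.25 for Actb.

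The arrays did not separate fully by group. Over 31761 probes detected on every array with no missing spot, the first principal component held 65.1% of the variance. It placed control replicate 1 at -45.1 and control replicate 3 at -20.5. Control replicate 2 was at 8.66, next to PTH replicate 1 at 11.6, with PTH replicates 2 and 3 at 17.6 and 27.7. Across probes, which are not independent replicates, control replicate 2 correlated with PTH replicates 1, 2 and 3 at 0.9980, 0.9975 and 0.9966, and with control replicates 1 and 3 at 0.9923 and 0.9971.

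A set of 115 probes varied most across the arrays, with an SD of at least 1 on the log2 scale. Of these, 111 were higher on average in PTH, by a median of 1.98 over the 115 on the log2 scale (quartiles 1.58 and 2.39), and 84 had every PTH array above every control array. Only 2 passed the adjusted test in limma, the same 2 as above, and 86 reached an unadjusted p under 0.05. Their level also varied among controls, with a median range of 1.81 on the log2 scale, which the choice of variable probes partly sets.

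**Figure D3:**
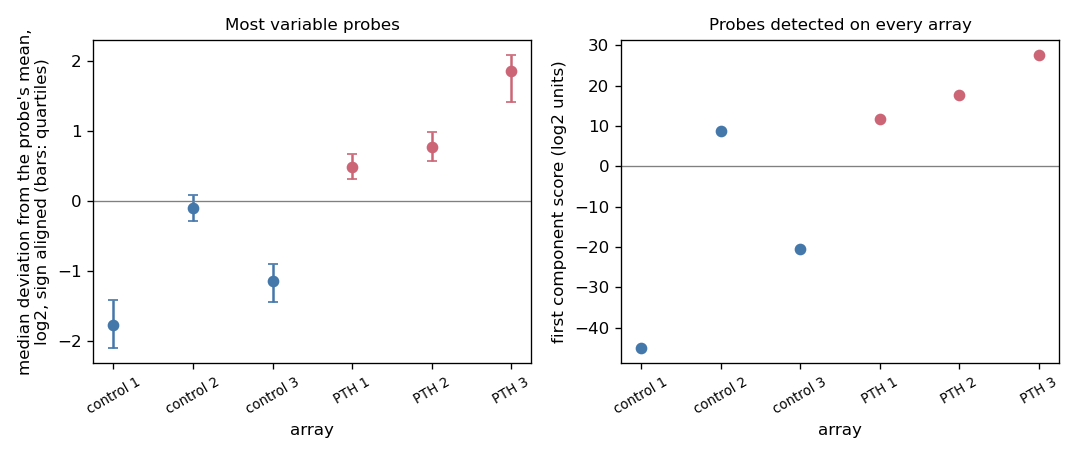
Left, median deviation of the 115 most variable probes from each probe's mean on each array (log2, with the sign turned for probes that run against the first component), with quartiles as bars; right, score of each array on the first component over 31761 probes. Control replicate 2 lies at -0.11 on the left and 8.66 on the right, between the other controls and the PTH arrays.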

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

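The tests of the slide neighbourhood were chosen before their result was seen, and the other tests here after. A control spot outside the comparisons, an adenovirus E1A spike-in probe, was flagged because every PTH array lay above every control array: it was 0.14 higher on the log2 scale, at -1.58 ± 0.07 against -1.71 ± 0.05 (SD, n = 3 each). Of 16 control probes detected on every array 1 was above and 3 were below in this way, against 0.80 in each direction by chance.

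The 2 probes that rose were weighed against a local artefact on the slide. The usable spots within 2 rows and columns of each had median log2 differences of 0.053 and 0.025, far under the changes of 2.41 and 1.94, which argues against it. The real split of the 6 arrays called 2 probes, both at least 2-fold, and the highest of the other splits 0; 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. For lincRNA-named probes all 10 splits gave as many as the real one, 0, and the highest other split also gave 0. A response to PTH is a hypothesis that may account for these 2 probes.

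Control replicate 2 lay between the other controls and the PTH arrays. That it holds PTH-treated RNA stays open: on probes chosen without it and without 1 PTH array, on a scale from the other controls (0) to PTH (1), its medians were 0.55, 0.53 and 0.69, against 0.68, 0.84 and 1.504 for the left-out PTH replicates 1, 2 and 3, and its quartiles overlapped those of PTH replicate 1. On the 2 probes that rose, it lay with the other controls, at 0.062 or less, against 0.96 to 1.03 for the PTH arrays. These 2 also had the smallest p in limma without control replicate 2, so their choice did not rest on it. On them it was unlike a PTH array, but 2 probes cannot settle this for that array. Signal-dependent scaling is argued against, since after quantile normalization 5251 probes still passed without it. Unequal signal from the ends of transcripts may contribute and stays open. It was weighed on control spots whose names end in 3 or 5. That these digits stand for transcript ends is a hypothesis, not stated with the data. The difference between PGK1 spots whose names end in 3 and in 5 correlated with the first component (r = 0.94, exact permutation p = 0.021, adjusted 0.042 over 6 relations, n = 6). By rank, rho was 0.71 (exact permutation p = 0.14, adjusted 0.14, n = 6). For GAPDH r was 0.89 (exact permutation p = 0.021, adjusted 0.042, n = 6), with the same rho. Without control replicates 1 and 3, r was -0.12 for PGK1 and -0.28 for GAPDH, so the relation rests on those samples. They are also the arrays that lie apart from the others on the component, so r without them cannot weigh this explanation. The PGK1 difference was 7.02 and 7.33 on control replicates 1 and 3, and 7.57 on control replicate 2. On PTH replicates 1, 2 and 3 it was 7.61, 7.497 and 7.58. For GAPDH these values were 1.195 and 1.357, then 1.533, then 1.673, 1.509 and 1.549. Control replicate 2 lay within the PTH range on both. Slide order, in which all control arrays come before all PTH arrays, also went with the first component. For it rho was 0.94 (exact permutation p = 0.017, adjusted 0.050, n = 6). By value, r was 0.83 (exact permutation p = 0.036, adjusted 0.043, n = 6), or 0.45 without the 2 farthest arrays. The count without control replicate 2 therefore cannot tell PTH from this signal difference or from place on the slide.

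Most of the 115 most variable probes moved together, 70 of them in 1 order of the 6 arrays, among 31 orders seen. The 2 called probes are in the set, but the controls differed little on them. Their control SD was 0.02 for ASMM10P011129 and 0.08 for ASMM10P011130 on the log2 scale. PTH alone as the whole cause was weighed on pairs of control arrays, on probes chosen on the other 4 arrays. The median log2 difference was 1.56 between control replicates 1 and 2, 0.96 between 2 and 3 and 0.20 between 1 and 3. The lower quartiles of the first 2 pairs, 0.82 and 0.60, lay above the 0.61 and 0.38 that bound 95% of all probes. For replicates 1 and 3 the median lay under the bound of 0.33. Both pairs that differed hold control replicate 2. Whether that array holds PTH-treated RNA stays open, though it lay with the other controls on the 2 probes that rose. The differences between control pairs argue against PTH alone only if that array was untreated, as labelled. A part played by PTH stays open. The PGK1 difference also went with these probes (r = 0.83, exact permutation p = 0.035, adjusted 0.043; rho = 0.71, exact permutation p = 0.14, adjusted 0.14, n = 6), but r was 0.01 without control replicates 1 and 3, and for GAPDH r was 0.80 (exact permutation p = 0.057, adjusted 0.057, n = 6) and -0.11 without them. Place on the slide could not be told apart from group: rho with slide order was 0.94 (exact permutation p = 0.017, adjusted 0.050) and r was 0.91 (exact permutation p = 0.017, adjusted 0.042, n = 6), or 0.65 without the 2 farthest arrays. A sequence shared by these probes may also be a cause, but no probe sequences were used here. The share of their variation on 1 component, 76.4%, cannot tell, since over all probes compared it was 65.1%.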

How the results depend on the processing

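Leaving out each array in turn gave 2 to 5560 probes, 2 to 275 at least 2-fold and 0 to 36 lincRNA-named, and the count was 2 except without control replicate 2. Without that array, 10 splits of the remaining arrays, on probes with no missing spot, gave 5613 for the real split and 0 for the highest other. The array left out is the one that lay between the groups on the first component. Its removal therefore favours the real split, and this contrast is no independent evidence for PTH. The remaining arrays also split by group on the PGK1 and GAPDH differences between spots named 3 and 5, and by slide order. The count without control replicate 2 therefore cannot tell PTH from this signal difference or from place on the slide. Array weights gave 12150 probes, 262 at least 2-fold and 99 lincRNA-named; they gave control replicate 3 a weight of 13.6 and control replicate 2 one of 0.31, and another split gave 9268, so the weighted count follows a structure of the samples. The unadjusted threshold with at least 2-fold gave 185 probes and 5 lincRNA-named. With the replicate block 9 passed, 7 at least 2-fold, and 2 on the probes with no missing spot; the numbers did not pair the samples (correlations of deviations 0.19, -0.03 and -0.13), and not every sample correlated best with its own number. Chosen after seeing the data, the slide row as a block gave 16 probes and the upper row alone 11, all at least 2-fold; both take the PTH effect from 1 PTH array. Without the 115 most variable probes 0 passed, because both called probes are among those removed. Quantile normalization, median centring, other dim filters, normexp and no trend gave 2 or 3, and both called probes passed in each. Both stayed past the threshold in the 16 alternatives with at least 2 PTH arrays that tested them, with log2 changes of 2.24 to 2.46 and 1.80 to 1.98 and adjusted p up to 0.0017 and 0.0039. The 2 lower probes passed with array weights and without control replicate 2, in 2 of 19 alternatives. Gapdh reversed to -0.0048 with quantile normalization. Camera and fry were not run, as no list had a named member; the mean of a gene's probes and the slide as a block could not be made. Signal over background limits the dim probes. Causes not named here were not tested.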

Other observations

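All tests here were chosen after the values were seen. Of 876 lincRNA loci with a probe on each strand, the mouse-named ones had both strands detected on all arrays at 14 of 317 loci, 1 strand at 93 and neither at 210, against 11.5 with both if the strands were independent (odds ratio 1.37, 95% confidence interval 0.64 to 2.79). The human-named ones had both at 19 of 547 loci, against 14.7 (odds ratio 1.46, 95% confidence interval 0.78 to 2.64). Fisher's exact test gave adjusted p of 0.37 and 0.32 for these classes, and 0.14 for the 12 exon loci, where 3 had both, so an association between strands was not shown.

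The 2 probes that rose have consecutive numbers. A hypothesis that consecutive numbers mark probes of 1 transcript was tested on 24201 such pairs, where the mean levels correlated at 0.055 and the log2 differences at 0.051 across probes, which are not independent replicates. At a gap of 50 in number these were 0.016 and 0.010. Probes of 1 transcript can differ in affinity, and no pairs known to share a transcript were used here, so the hypothesis stays open.

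Probes well above background on all 3 control arrays and no PTH array numbered 94, and 0 showed the opposite. Other splits of the arrays gave up to 717, and PTH replicate 2, with the widest spread of negative control spots, has the lowest detection. With PTH values raised to at least the detection floor, none of the 94 reached a 2-fold decrease, and the highest was 1.47-fold. This gives only a lower bound on each decrease, so a 2-fold decrease is not excluded.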
